A study of Homo sapiens with 12 samples.

How the data were processed

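RNA was measured in 12 libraries from a pair of human melanoma cell lines, A375 and its BRAF-inhibitor-resistant counterpart A375-BIR. Each line was grown in RPMI with 10% serum and given dabrafenib at 200 nM or 0.1% DMSO for 48 h, with 3 libraries per group. Per the labels, the authors made 3′ tag libraries (QuantSeq FWD, Lexogen) from 250 ng RNA and sequenced them as single-end reads of 100 bases on a NovaSeq instrument. The authors deposited 1 file per library of raw read counts per gene, with no normalization. The processing notes name the human build hg38. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Each file closes with 5 lines, named as htseq-count names them, for reads given to no gene; these were left out of every total and used only to describe the libraries.

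Of the 12 files, 10 list 33694 human genes and 2 list 31053 mouse genes. The mouse files are those of the second and the third A375 DMSO library, and their labels state human. They were left out of every comparison, because their counts cannot be set beside those of human genes. The design had been written for 12 libraries, so that A375 DMSO, planned with 3, entered with 1. No spread can be estimated within that group. The fit gives its library the spread pooled over the other groups. The A375 DMSO files carry a different run stamp from the other 9, so that run and group cannot be told apart in any comparison with that group. Both A375-BIR groups and A375 with dabrafenib share a run stamp.

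Gene counts per library ranged from 198690 to 1999840 with a median of 570083. A count of 0 in a library allows a level of up to 1.5 to 15.1 CPM (3 counts of its raw total). By TMM-scaled totals, a count of 0 over a whole group allows up to 1.09 CPM in A375-BIR with DMSO, 1.49 in A375-BIR with dabrafenib, 1.88 in A375 with DMSO and 2.70 in A375 with dabrafenib. The lone A375 DMSO library thus has a limit of 1.5 CPM on the first scale and 1.88 on the second. Counts on genes made up 20.4% to 31.1% of each human library's lines in total. Reads outside annotated genes took 28.6% to 31.0% in the 9 libraries of the shared run and 20.1% in the A375 DMSO library, and reads with more than 1 alignment took 40.0% to 49.4% and 52.5%. Of 33694 human identifiers listed, symbols were found for 32807, and 33132 are in GENCODE 29 (GRCh38), from which types and positions were taken.

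Genes were kept by filterByExpr at its defaults (minimum count 10), which left 10236. The filter takes the smallest group as the number of libraries that must pass, here 1. Without the A375 DMSO library it left 8736. Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust = TRUE, 1 coefficient per group, 10 libraries, 6 residual degrees of freedom). The common biological coefficient of variation was 0.136. The 5 comparisons were each line's response to dabrafenib, the lines in DMSO, the lines in dabrafenib, and the difference between the responses. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels in CPM use TMM-scaled totals. For a group with no counts of a gene, the fold is given as a lower limit against 3 counts over the group. With 1 to 3 counts it is the ratio of summed counts with an exact 95% counting interval.

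A set of 37 gene lists was fixed, with their members, before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternatives, except where a later choice is stated. Each list was tested with camera in limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation beside it, and adjusted over the lists of a comparison. The leukocyte and erythroid list and the endothelial list had fewer than 3 tested members and gave no result, which left 35. Members whose symbol found no match among those of the listed identifiers were SOD2 of the NF-kB list, BAGE and CSAG3 of the cancer-testis antigens, H3C2 and H3C3 of the histones, and 12 of the 16 of the nuclear RNA list. With the preset correlation 16 lists were called in the response of A375-BIR, 12 in that of A375, 9 between the lines in DMSO, 17 in dabrafenib and 9 in the difference between responses. With an estimated correlation 2, 2, 0, 0 and 0 of these held. Fry, which asks whether a list's genes move 1 way on balance and compares them with no other genes, called 11, 16, 22, 24 and 13.

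The rule for named genes took, in each comparison of a pair of groups, the 10 highest and 10 lowest fitted changes among called genes with a symbol, at least 10 CPM in the higher group and groups that do not overlap. It added 19 key genes of the pathway and of melanoma states, and up to 4 members with the smallest p of each list described. For the difference between responses it took the 10 highest and 10 lowest and the key genes. Of the key genes MYC, MLANA and PDGFRB had 42, 1 and 38 counts in all and were not tested.

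The procedure was tested on simulated data with this design. Of 100 genes changed 2-fold it recovered 57 in the response of A375-BIR, 40 between the lines in dabrafenib, 33 in the response of A375, 47 between the lines in DMSO and 13 in the difference between responses. At 4-fold the numbers were 88, 85, 80, 83 and 65. False calls made up 5.30% to 12.4% of calls. The simulation held no difference between runs. For the comparisons that use A375 DMSO, this share therefore leaves out calls that a run difference would cause.

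The alternatives were DESeq2 size factors in edgeR, no filter, a mean count of at least 50, the replicate number as a block, mitochondrially encoded genes removed, counts thinned to the smallest library, DESeq2 1.42.0, limma-voom, a fit with only the groups compared, and each library left out in turn. The lone A375 DMSO library could not be left out of its own comparisons. A fit without that library and a fit without the third dabrafenib libraries of both lines were added after the data were seen.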

Results

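RNA from 2 human melanoma lines was profiled by 3′ tag sequencing, which counts reads near the polyadenylated end of transcripts. A375 is an established melanoma line with an activating BRAF mutation, and the labels name A375-BIR as its BRAF-inhibitor-resistant counterpart. Each line was treated for 48 h with dabrafenib, an inhibitor of the BRAF kinase, at 200 nM or with the solvent DMSO at 0.1%, giving 4 groups of 3 libraries. The values deposited by the authors are raw read counts per gene. The A375-BIR DMSO libraries held 1100917, 942861 and 579288 gene counts, and the A375-BIR dabrafenib libraries 971347, 560878 and 391210. The A375 dabrafenib libraries held 493398, 463378 and 198690, and the first A375 DMSO library 1999840. The files of the second and the third A375 DMSO library list mouse gene identifiers, with 224221 and 652439 gene counts, and entered no comparison. Every comparison that uses A375 DMSO therefore rests on 1 library, whose run stamp also differs from that of the 9 libraries of the other groups. In that library 15.1% of gene counts were mitochondrially encoded, against 4.63% to 7.21% in A375-BIR and 10.7% to 15.1% in A375 with dabrafenib. Levels below are mean read counts scaled to TMM-scaled library totals (CPM). They carry the SD over 3 libraries (n = 3), except A375 DMSO (n = 1, no SD). Log2 changes carry an approximate standard error, the size of the change divided by the square root of the F statistic of the edgeR test. Intervals and limits given for low counts cover counting error only. Positions come from GENCODE 29 (GRCh38).

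The response of the resistant line asked which genes differ between A375-BIR with dabrafenib and with DMSO, all from 1 run. BRAF, the drug target (chromosome 7, 140719327 to 140924928), stood at 53.8 ± 12.1 CPM with DMSO and 57.7 ± 5.29 CPM with dabrafenib and was not called (0.13 ± 0.22, adjusted p = 0.872). Of the 9 tested genes of the 10-gene MAPK output list (MPAS), 1 was lower and 8 were not called, over all genes and adjusted over the list alone. The median was -0.36 (camera adjusted p = 0.00178, adjusted p = 0.0867 with an estimated correlation). ETV4, an ERK-induced transcription factor, fell by 0.86 on the log2 scale. The ERK phosphatase gene DUSP6 (-0.36 ± 0.19), the ERK pathway inhibitor SPRY4 (-0.68 ± 0.29) and the transcription factor ETV5 (-0.55 ± 0.24) were not called. CCND1, the cyclin D1 gene, stood at 474 ± 10.6 CPM with DMSO and 478 ± 40.3 CPM with dabrafenib. Of 13 other ERK-dependent early genes, 2 were lower and none higher (5 lower adjusted over the list alone): IER3 (-0.70) and DUSP5 (-0.86), with a median of -0.30 (camera adjusted p = 0.0296, adjusted p = 0.163 with an estimated correlation). Of 14 RAF-MEK-ERK pathway components 0 were called, also when adjusted over the list alone (median -0.063, camera adjusted p = 0.804). The calls of ETV4, IER3 and DUSP5 did not hold when any 1 of several libraries was left out, while their direction did. The call of ETV4 ended without any of DMSO replicates 1, 2 and 3 or dabrafenib replicate 2 (-0.96 to -0.69 without 1 of them), that of IER3 without any DMSO replicate or dabrafenib replicate 3 (-0.78 to -0.50), and that of DUSP5 without any DMSO replicate or dabrafenib replicate 1 (-0.97 to -0.54). The list of other ERK-dependent genes lost its call without DMSO replicate 3 (median -0.31) and without dabrafenib replicate 3 (-0.32).

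Mitotic genes fell in A375-BIR. TOP2A, the topoisomerase of dividing cells (chromosome 17, 40388516 to 40417950), went from 1250.2 ± 40.0 to 605 ± 30.4 CPM, a log2 change of -1.05 ± 0.16 (adjusted p = 7.92e-05). MKI67, which encodes the proliferation marker Ki-67, went from 698 ± 42.6 to 417 ± 92.5 CPM (-0.75 ± 0.18). The mitotic kinase gene NEK2 went from 147 ± 15.1 to 41.7 ± 4.80 CPM (-1.81 ± 0.21). Of 29 tested members of the G2/M and mitosis list, 20 were lower and none was higher, and 25 were lower when adjusted over the list alone. Their median log2 change was -0.79 (camera adjusted p = 4.86e-43, adjusted p = 0.000691 with an estimated correlation). Examples were CDC20 (-1.51), which activates the anaphase-promoting complex, PTTG1 (-1.32), the securin gene, AURKA (-1.27) and PLK1 (-1.37), both mitotic kinases. CENPA, the centromeric histone, fell by 2.35 ± 0.59 on the log2 scale, CKS2, a CDK-binding subunit, fell by 1.79, PIF1, a DNA helicase, fell by 1.61, and CDKN2D, a CDK inhibitor, fell by 1.62. UCHL3 (-1.76), SWI5 (-1.70), TMEM60 (-1.52) and the noncoding MANCR (-1.49) completed the 10 lowest. Of 24 tested genes for DNA replication and S phase, 0 were called, also when adjusted over the list alone. Their median was 0.029 and their mean -0.016 (camera adjusted p = 0.423, adjusted p = 0.685 with an estimated correlation). Among the mitotic and lowest genes, the call of MKI67 ended without DMSO replicate 1, 2 or 3 (-0.79 to -0.70) and that of CENPA without dabrafenib replicate 1 (-2.08). That of CDKN2D ended without DMSO replicate 1 or 3 or dabrafenib replicate 1 or 3 (-1.81 to -1.38). UCHL3 (-1.77 to -1.59) and MANCR (-1.71 to -1.23) lost their calls without any DMSO replicate or dabrafenib replicate 1, and TMEM60 (-1.59 to -1.27) also without dabrafenib replicate 3. TOP2A, NEK2, CDC20, PTTG1, AURKA, PLK1, CKS2, PIF1 and SWI5 were called without each of the 6 libraries in turn.

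The extracellular matrix and TGF-beta list rose in A375-BIR, with 9 of 22 tested members higher, none lower and 13 not called, and also 9 higher when adjusted over the list alone. Its median log2 change was 0.49 (camera adjusted p = 3.36e-10, adjusted p = 0.027 with an estimated correlation). THBS1 (1.06) encodes thrombospondin, FN1 (0.91) fibronectin, TGFBI (0.78) a secreted matrix protein and BGN (1.00) the proteoglycan biglycan. Of 28 ATF4 target genes of the integrated stress response, 8 were higher and none lower, or 11 higher when adjusted over the list alone, with a median of 0.58. Camera gave an adjusted p = 3.38e-12, and the call was lost at an adjusted p = 0.073 with an estimated correlation. The amino acid transporter genes SLC7A5 (1.22) and SLC7A11 (1.00), and ALDH1L2 (1.25), a mitochondrial folate enzyme, were among those that rose. Among the 10 highest, C3 went from 6.30 ± 1.07 to 47.4 ± 15.4 CPM (2.86 ± 0.37), C1R from 4.91 ± 2.81 to 32.4 ± 6.14 CPM (2.70 ± 0.40), CFI from 2.03 ± 1.22 to 13.7 ± 3.59 CPM (2.83 ± 0.64), and the cytokine gene IL6 from 3.21 ± 1.12 to 18.9 ± 7.53 CPM (2.56 ± 0.56). MAP2, a microtubule protein of neurons, rose by 3.14 ± 0.52 and LRRC7 by 2.77 ± 0.72 on the log2 scale. The remaining 4 held 3 counts or fewer in DMSO. ANGPTL7 had a ratio of 41.3 (95% counting interval 6.86 to 1684), OLFML2A of 32.3 (8.47 to 275), DCT, a melanin synthesis enzyme, of 22.01 (5.62 to 189.6), and CHAC1, a glutathione-degrading ATF4 target, of 11.9 (3.65 to 61.5). DCT stood at 1746 ± 208 CPM in A375 with dabrafenib, and carry-over of 0.870% of that level would give its rise to 16.3 ± 8.65 CPM here. ACAN, at 250 ± 44.3 CPM there and 0 counts here, limits a share common to all genes to 0.598%. With so few counts carry-over was still not excluded as the source of DCT. The calls of FN1 (0.79 to 0.88), TGFBI (0.75 to 0.77) and CFI (2.52 to 2.75) ended without DMSO replicate 1 or 2. BGN (0.81 to 1.05) and LRRC7 (2.32 to 3.14) lost theirs without any DMSO replicate or dabrafenib replicate 1. IL6 lost its call without DMSO replicate 2 or dabrafenib replicate 1 (2.29 to 2.45), and CHAC1 without dabrafenib replicate 1 (fitted log2 2.10, which is no bound).

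Further lists were called by camera in A375-BIR and lost the call with an estimated correlation. Of 23 genes of the AXL-high dedifferentiated state, 5 were higher and none lower (7 higher and 1 lower adjusted over the list alone), among them ABCC3, an efflux transporter (2.52, median 0.12, camera adjusted p = 0.00177, adjusted p = 0.102 with an estimated correlation). Of 21 YAP/TAZ targets, 2 were higher, TGFB2 (1.39) and CCDC80 (0.80), or 4 adjusted over the list alone (median 0.26, camera adjusted p = 0.00177, adjusted p = 0.159 with an estimated correlation). Of 16 NF-kB and cytokine genes, 4 were higher and 1 lower, also when adjusted over the list alone, including TNFAIP2 (1.11) and the inhibitor NFKBIA (0.75), with a median of 0.45 (camera adjusted p = 0.00728, adjusted p = 0.183 with an estimated correlation). Thinning every library to the smallest total turned the direction of that list's test, at a median of 0.042. Of 27 type I interferon response genes, 1 was higher, XAF1 (2.94), or 6 adjusted over the list alone (median 0.40, camera adjusted p = 0.00431, adjusted p = 0.523 with an estimated correlation). Of 21 antigen presentation genes 0 were called, also adjusted over the list alone (median 0.34, camera adjusted p = 0.00728, adjusted p = 0.183 with an estimated correlation). Of 24 axon guidance genes, 2 were higher, SEMA3C (1.00) and EFNA5 (0.92), or 3 higher and 1 lower adjusted over the list alone (median 0.38, camera adjusted p = 0.00904, adjusted p = 0.102 with an estimated correlation). Of 5 drug efflux transporters 1 was higher, ABCC3, or 2 adjusted over the list alone (median 0.32, camera adjusted p = 0.00967, adjusted p = 0.113 with an estimated correlation). Dabrafenib replicate 2 decided 4 of these list calls, which ended without it: the AXL-high state (median 0.086), YAP/TAZ (0.21), NF-kB (0.23) and antigen presentation (0.37). The interferon list lost its call without dabrafenib replicate 1 (0.15). Of the genes, CCDC80 (0.77) and SEMA3C (0.84) lost their calls without DMSO replicate 1, and XAF1 (2.62 to 3.91), EFNA5 (0.86 to 1.01) and NFKBIA (0.74 to 0.78) without any DMSO replicate. NFKBIA also lost it without dabrafenib replicate 2 (0.49).

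On the lower side, 0 of 23 cholesterol biosynthesis genes were called, or 1 lower adjusted over the list alone, MSMO1 (-0.85), a sterol oxidase (median -0.49, camera adjusted p = 0.000864, adjusted p = 0.246 with an estimated correlation). Of 40 nuclear-encoded oxidative phosphorylation genes 0 were called in either way, adjusted over the list alone included (median -0.21, camera adjusted p = 0.000982, adjusted p = 0.523 with an estimated correlation). Of 5 replication-dependent histone genes, whose transcripts lack poly(A) tails, 1 was lower, H1-2 (-0.68), or 3 adjusted over the list alone (median -0.71, camera adjusted p = 0.00177, adjusted p = 0.0867 with an estimated correlation). Of 17 heat shock and handling genes 0 were called, also adjusted over the list alone (median -0.24, camera adjusted p = 0.0242, adjusted p = 0.173 with an estimated correlation). 5 lists were called by camera in none of the 5 comparisons, besides the pathway components above. Of 20 ER unfolded protein response genes 1 was lower, SEC24D (-0.84), also adjusted over the list alone (median 0.064, mean -0.057, camera adjusted p = 0.423). Of 14 BCL2 family genes 1 was lower, the survival gene BCL2L1 (-0.82), also adjusted over the list alone (median -0.021, camera adjusted p = 0.378). Of 13 CDK inhibitor and RB family genes 1 was lower, CDKN2D, or 1 higher and 1 lower adjusted over the list alone (median -0.084, camera adjusted p = 0.378). Of 26 lysosome and autophagy genes 0 were called, also adjusted over the list alone (median 0.038, camera adjusted p = 0.423), as were 0 of 4 fibroblast markers (median 0.25, camera adjusted p = 0.804). The heat shock list lost its call without DMSO replicate 3 (-0.21) or dabrafenib replicate 3 (-0.17), and oxidative phosphorylation without the latter (-0.043). The ER list was called lower without dabrafenib replicate 2 (-0.18), as was MSMO1 (-1.35), which was also called without DMSO replicate 2 (-1.01). The call of H1-2 (-0.75 to -0.57) ended without any DMSO replicate or dabrafenib replicate 1 or 3. SEC24D (-0.77 to -0.73) and BCL2L1 (-0.76 to -0.73) lost theirs without DMSO replicate 1 or 3, SEC24D also without dabrafenib replicate 1, and CDKN2D as given above (-1.81 to -1.38).

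Across all genes, 139 were higher and 113 lower in A375-BIR with dabrafenib, of 10236 tested, and 82 and 47 of them at least 2-fold. The share of MALAT1, a nuclear RNA, was 2.54% to 3.18% with DMSO and 2.36%, 3.94% and 5.78% with dabrafenib. Mitochondrially encoded genes took 4.63% to 5.49% with DMSO and 5.17%, 4.88% and 7.21% with dabrafenib, with a median log2 change of 0.22. In the third dabrafenib library 20.4% of reads lay on genes, against 27.7% and 28.6% in the first and second, and 49.4% had more than 1 alignment. The count of 252 depended on single libraries and on the method: it was 106, 140 and 107 without A375-BIR DMSO replicate 1, 2 and 3, and 558 without A375-BIR dabrafenib replicate 2. It was 106 by DESeq2, 125 with the fit restricted to these 6 libraries, 137 with a mean count of at least 50 and 61 with thinned counts.

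**Figure D1:**
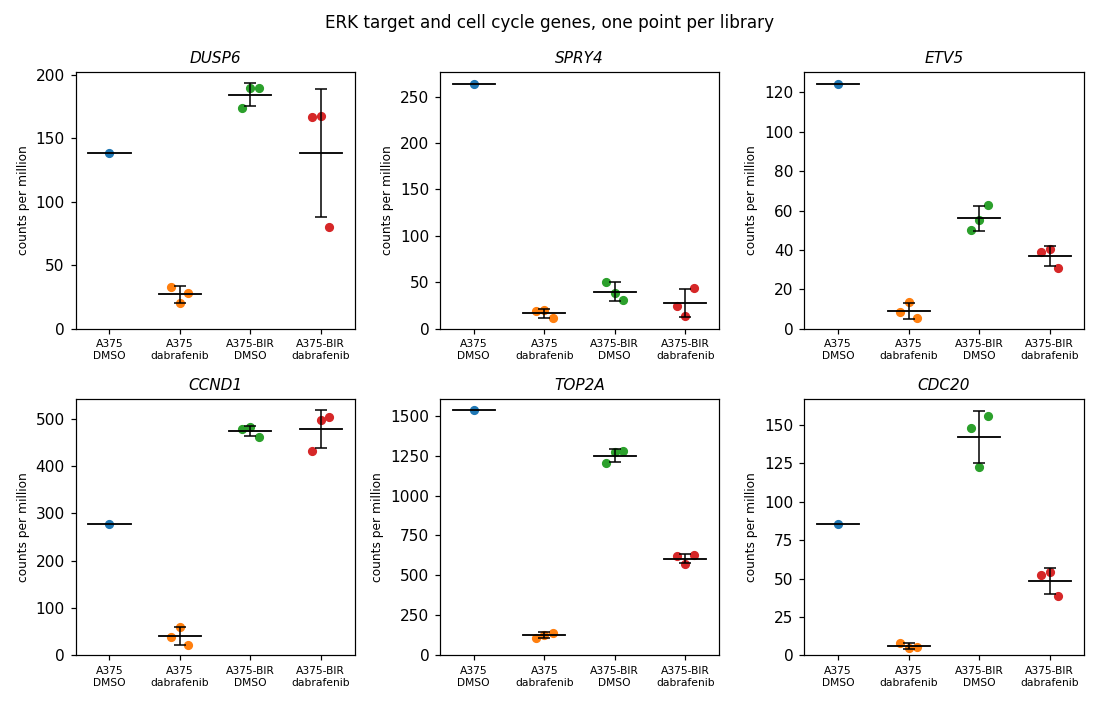
Each panel shows one gene in CPM (vertical axis, from 0) for the 4 groups, with one point per library, a line at the group mean and a bar of 1 SD where a group has 3 libraries. CCND1 stayed at 474 and 478 CPM in A375-BIR with DMSO and dabrafenib and stood at 278 and 40.7 CPM in A375, while TOP2A fell from 1250.2 to 605 CPM in A375-BIR.

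The lines were next compared under the same drug, A375-BIR against A375 with dabrafenib, again within 1 run. BRAF was not called, at 57.7 ± 5.29 against 46.0 ± 6.08 CPM (0.31 ± 0.27). Of 9 MAPK output genes, 5 were higher and 3 lower, also adjusted over the list alone, with a median of 1.91, and the list was not called (camera adjusted p = 0.0866, adjusted p = 0.22 with an estimated correlation). AXL, a receptor tyrosine kinase gene (chromosome 19, 41219203 to 41261766), stood at 298 ± 29.02 CPM in A375-BIR and 5.09 ± 5.64 CPM in A375 (log2 difference 5.52 ± 0.33, adjusted p = 2.77e-16). EGFR stood at 216 ± 31.8 CPM in A375-BIR against 3 counts over the A375 group, a ratio of 77.6 (95% counting interval 26.4 to 378). SOX10, a transcription factor of the melanocyte and neural crest lineage (chromosome 22, 37970686 to 37987422), stood at 53.8 ± 17.2 against 962 ± 27.6 CPM (-4.16 ± 0.21). NGFR, a neural crest receptor, stood at 3.62 ± 1.09 against 273.2 ± 13.2 CPM (-6.04 ± 0.31), and the receptor kinase ERBB3 at 18.8 ± 0.601 against 187 ± 29.3 CPM (-3.33 ± 0.26). MITF, the melanocyte master regulator, was lower by a smaller margin (-0.46 ± 0.19, adjusted p = 0.0421). That call ended without A375-BIR dabrafenib replicate 1 (-0.42) or 3 (-0.40), without A375 dabrafenib replicate 1 (-0.21), and under 7 other settings, DESeq2 (-0.44) among them.

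Of 23 tested AXL-high dedifferentiation genes, 17 were higher and 2 lower in A375-BIR (17 and 3 adjusted over the list alone), with a median of 1.91. Camera gave an adjusted p = 1.37e-09, and the adjusted p = 0.0958 with an estimated correlation. Examples were NT5E (4.94), a surface nucleotidase, and TCF4, with a ratio of 129.9 (95% counting interval 23.1 to 5153). Of 21 YAP/TAZ targets, 15 were higher and 2 lower (15 and 3 adjusted over the list alone), led by ANKRD1, with a ratio of 199 (95% counting interval 55.0 to 1649), and CRIM1 (3.74), with a median of 1.53 (camera adjusted p = 1.20e-09, adjusted p = 0.0707 with an estimated correlation). Of 16 receptor tyrosine kinases and ligands, 10 were higher and 3 lower (11 and 3 adjusted over the list alone), MET (1.75) among them, with a median of 1.33, or 1.23 with 2 genes at their bound (camera adjusted p = 0.0061, adjusted p = 0.134 with an estimated correlation). Of 19 melanocyte lineage genes, 13 were lower and 1 higher (14 and 1 adjusted over the list alone), with DCT at -6.75 and GPNMB at -2.53, and a median of -2.53 (camera adjusted p = 2.69e-14, adjusted p = 0.0707 with an estimated correlation). Of 10 neural crest-like genes, 5 were lower and 2 higher, also adjusted over the list alone, with SOX2 at -1.97 and SEMA3B at 1.23 (median -1.10, or -1.04 with 1 gene at its bound, camera adjusted p = 0.00284, adjusted p = 0.134 with an estimated correlation).

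Interferon and proliferation genes were higher in A375-BIR. Of 27 type I interferon response genes, 20 were higher and 2 lower, also adjusted over the list alone: ISG15 (4.86), an interferon-induced ubiquitin-like protein, IFI27 (4.32) and IFIT3 (2.81) were examples, with a median of 2.81, or 2.74 with 4 genes at their bound (camera adjusted p = 3.13e-09, adjusted p = 0.253 with an estimated correlation). Of 21 antigen presentation genes, 12 were lower and 2 higher, also adjusted over the list alone, with HLA-DRB1 (-3.83), HLA-DPA1 (-3.19) and CD74 (-2.67) lower and a median of -0.74 (camera adjusted p = 6.86e-07, adjusted p = 0.128 with an estimated correlation). Of 29 G2/M genes, 25 were higher (26 adjusted over the list alone), with MKI67 at 3.30 ± 0.26 and TOP2A at 2.30 ± 0.20 (median 2.18, camera adjusted p = 2.82e-13, adjusted p = 0.0707 with an estimated correlation). Of 24 S phase genes, 16 were higher and 1 lower (18 and 1 adjusted over the list alone), including the ribonucleotide reductase genes RRM2 (2.48) and RRM1 (1.53), with a median of 1.34 (camera adjusted p = 0.0005, adjusted p = 0.168 with an estimated correlation). CCND1 was higher at 3.42 ± 0.23, DUSP6 at 2.40 ± 0.29 and ETV5 at 1.91 ± 0.40, while SPRY4 was not called (0.51 ± 0.42). Of 20 p53 targets, 10 were lower and 2 higher (11 and 2 adjusted over the list alone): MDM2 (-1.81), SESN2 (-1.58) and CDKN1A (-1.35 ± 0.21), with a median of -0.52 (camera adjusted p = 0.022, adjusted p = 0.36 with an estimated correlation), a call lost without A375-BIR dabrafenib replicate 3 (-0.50). Of 28 ATF4 targets, 18 were lower and 4 higher, also adjusted over the list alone, with DDIT3 (-2.70) lower and STC2 higher at a ratio of 201 (95% counting interval 55.4 to 1660.1) (median -0.92, camera adjusted p = 0.00148, adjusted p = 0.131 with an estimated correlation). Of 30 ribosome biogenesis and MYC target genes, 16 were higher and 1 lower, also adjusted over the list alone, such as NOLC1 (1.65) and FBL (1.32), with a median of 0.58 (camera adjusted p = 0.00583, adjusted p = 0.207 with an estimated correlation). Of 16 NF-kB and cytokine genes, 9 were higher and 1 lower (10 and 1 adjusted over the list alone), with TNFAIP2 at 2.16 (median 1.31, camera adjusted p = 0.00642, adjusted p = 0.183 with an estimated correlation).

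Classes that report on RNA and library quality also differed between the lines in dabrafenib. Of 59 ribosomal protein genes, 43 were higher in A375-BIR (45 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 2.76e-09, adjusted p = 0.429 with an estimated correlation). Of 13 mitochondrially encoded genes, 12 were lower, also adjusted over the list alone, with a median of -1.20 (camera adjusted p = 9.41e-07, adjusted p = 0.348 with an estimated correlation). All 3 tested nuclear RNAs, NEAT1 (-1.37), KCNQ1OT1 (-1.18) and MALAT1 (-0.80), were lower, also adjusted over the list alone, with a median of -1.18 (camera adjusted p = 0.0212, adjusted p = 0.357 with an estimated correlation). MALAT1 took 5.08% to 8.60% of gene counts in A375 with dabrafenib. The call of these RNAs as a list ended without A375-BIR dabrafenib replicate 1 (-0.94) or A375 dabrafenib replicate 3 (-1.01). That of MALAT1 ended without either of them (-0.50 and -0.48) or A375-BIR dabrafenib replicate 2 (-0.78). All 3 tested epithelial markers, KRT18, KRT8 (1.81) and SFN, were higher, also adjusted over the list alone, and their median of 6.67 became 2.65 with 2 genes at their bound (camera adjusted p = 0.00125, adjusted p = 0.134 with an estimated correlation).

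Among single genes, the 10 highest in A375-BIR had no counts in A375 with dabrafenib, so each fold is a lower limit against 3 counts over the group. They were IGFN1 (at least 111-fold higher), AMIGO2 (86.2), KRT18, a simple-epithelium keratin (77.6), IGFBP7 (65.2), KISS1 (61.2), the embryonic globin gene HBE1 (57.7), RGS4 (49.8), ADAMTS12 (48.1), HAPLN1 (40.9) and PXDN (37.2). The 10 lowest had no counts in A375-BIR with dabrafenib: ACAN, the aggrecan gene, was at least 172-fold lower, NDN 62.1, TRPM8 57.9, EMILIN1 56.7, PCSK6 50.05, TRIM63 44.0, GASK1B 44.0, PKNOX2 42.2, PPP1R3C 30.8 and ACSS3 28.3. Both sets were limited to genes whose groups do not overlap, which chance alone gives for 10% of genes with 3 against 3. In all, 2309 genes were higher and 2065 lower in A375-BIR, 1627 and 1394 of them at least 2-fold. With counts thinned to the smallest library the numbers were 1292 and 1201, and with a mean count of at least 50 they were 900 and 864.

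**Figure D2:**
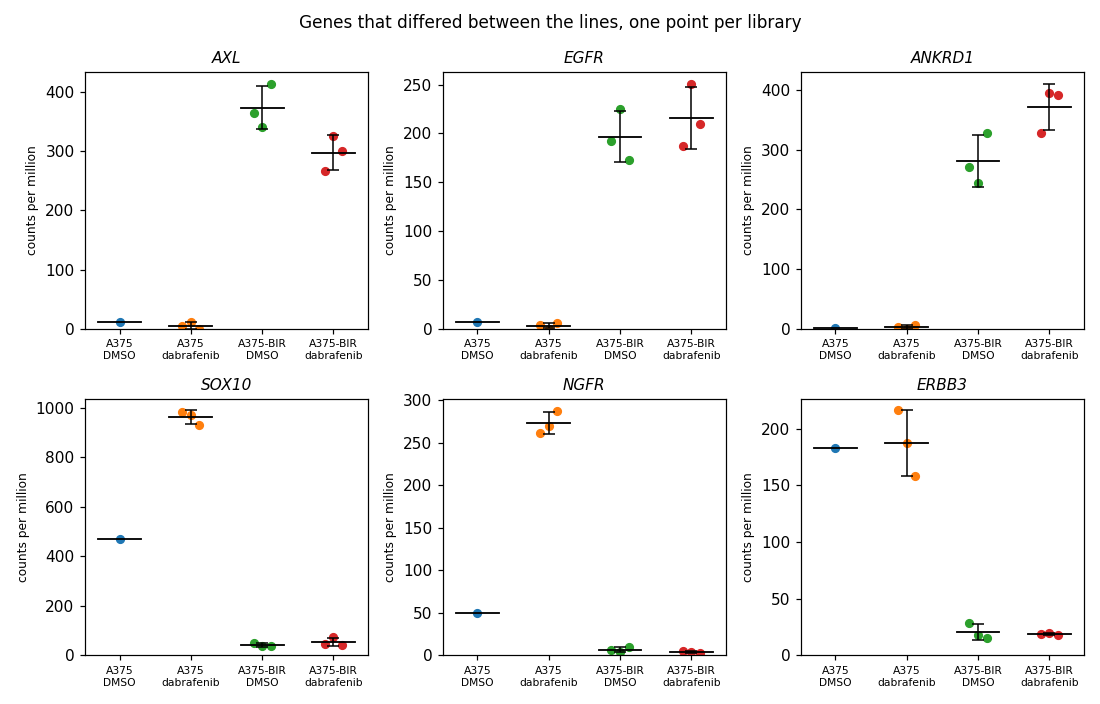
Each panel shows one gene in CPM (vertical axis, from 0) for the 4 groups, with one point per library, a line at the group mean and a bar of 1 SD where a group has 3 libraries. AXL stood at 298 CPM in A375-BIR and 5.09 CPM in A375 with dabrafenib, and SOX10 at 53.8 and 962 CPM.

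For the response of A375 itself, dabrafenib was compared with the lone A375 DMSO library, assumed to vary like the other groups, so that drug and run cannot be told apart. BRAF stood at 18.8 CPM with DMSO and 46.0 ± 6.08 CPM with dabrafenib (1.33 ± 0.37), a call that ended with thinned counts (0.43). Both A375-BIR groups, at 53.8 ± 12.1 and 57.7 ± 5.29 CPM, lay nearer to A375 with dabrafenib. The lone DMSO library was thus the one apart, so this rise cannot be assigned to dabrafenib. ERK output and cell cycle genes were lower with dabrafenib. CCND1 (chromosome 11, 69641087 to 69654474) stood at 278 CPM with DMSO and 40.7 ± 18.9 CPM with dabrafenib (-2.64 ± 0.27, adjusted p = 1.28e-09), DUSP6 at 138 and 27.1 ± 6.53 CPM (-2.35 ± 0.33), SPRY4 at 264 and 16.6 ± 4.70 CPM (-3.87 ± 0.33) and ETV5 at 124 and 9.09 ± 3.94 CPM (-3.63 ± 0.37). Of 9 MAPK output genes, 7 were lower and 1 higher, also adjusted over the list alone, ETV4 (-4.62) among them, with a median of -2.35 (camera adjusted p = 1.10e-06, adjusted p = 0.044 with an estimated correlation). Of 13 other ERK-dependent genes, 5 were lower, also adjusted over the list alone, including EGR1 (-2.97) and IER3 (-2.89), with a median of -0.65 (camera adjusted p = 0.00487, adjusted p = 0.18 with an estimated correlation). Of 29 G2/M genes, 25 were lower (26 adjusted over the list alone), with TOP2A at -3.65 ± 0.23, MKI67 at -3.16 ± 0.29 and AURKA at -2.62 (median -2.06, camera adjusted p = 2.98e-17, adjusted p = 0.044 with an estimated correlation). Of 24 S phase genes, 14 were lower, also adjusted over the list alone, including MCM7 (-3.14), part of the replicative helicase, CDT1 (-2.72) and CLSPN (-2.34), with a median of -1.47 (camera adjusted p = 4.69e-05, adjusted p = 0.175 with an estimated correlation).

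NGFR rose in A375 from 50.2 to 273.2 ± 13.2 CPM (2.43 ± 0.27) and SOX10 from 471 to 962 ± 27.6 CPM (1.03 ± 0.24), and MITF fell from 411 to 245 ± 60.7 CPM (-0.71 ± 0.22). Of 10 neural crest-like genes, 4 were higher and 2 lower (6 and 4 adjusted over the list alone), with ANXA1 at 2.58 and CNN3 at 2.81 (median 1.39, camera adjusted p = 0.0175, adjusted p = 0.175 with an estimated correlation). Of 21 YAP/TAZ targets, 8 were higher and 1 lower, also adjusted over the list alone, including AMOTL2 (2.97) and LATS2 (1.79), with a median of 0.76 (camera adjusted p = 0.0316, adjusted p = 0.349 with an estimated correlation). Of 28 ATF4 targets, 14 were higher and 1 lower (15 and 1 adjusted over the list alone), with NUPR1 (3.25), PCK2 (3.82), DDIT3 (1.65) and ASNS (1.71) higher (median 1.05, camera adjusted p = 3.87e-05, adjusted p = 0.175 with an estimated correlation). Of 21 hypoxia response genes, 11 were higher (12 adjusted over the list alone), such as ANKRD37 (4.27), HILPDA (2.66) and the glucose transporter SLC2A1 (1.95), with a median of 1.03 (camera adjusted p = 4.35e-05, adjusted p = 0.181 with an estimated correlation). Of 22 glycolysis genes, 12 were lower and 6 higher, also adjusted over the list alone, with GAPDH (-2.30) and ENO1 (-1.78) lower (median -0.71, camera adjusted p = 0.0466, adjusted p = 0.408 with an estimated correlation). Of 40 oxidative phosphorylation genes, 15 were lower and 3 higher (15 and 4 adjusted over the list alone), including UQCRC1 (-2.02) and NDUFB10 (-2.44), with a median of -0.29 (camera adjusted p = 0.0444, adjusted p = 0.742 with an estimated correlation). Of 30 ribosome biogenesis and MYC target genes, 17 were lower and 2 higher (19 and 2 adjusted over the list alone), among them BOP1 (-2.62), LYAR (-1.95) and FBL (-1.65), with a median of -0.94 (camera adjusted p = 0.00883, adjusted p = 0.284 with an estimated correlation). Of 59 ribosomal protein genes, 39 were lower (41 adjusted over the list alone), with RPS28 at -2.68, RPS20 at -2.19 and RPL6 at -2.20 (median -1.38, camera adjusted p = 4.78e-18, adjusted p = 0.349 with an estimated correlation). Ribosomal protein genes took 7.67% of gene counts in the DMSO library and 4.39%, 4.25% and 3.25% with dabrafenib. MALAT1 took 2.60% in the DMSO library and 5.08%, 5.68% and 8.60% with dabrafenib, and was not called (1.08 ± 0.45). Of 3 tested nuclear RNAs, 1 was higher, KCNQ1OT1 (1.18), and none lower (2 higher adjusted over the list alone), with a median of 1.08, and the list was not called (camera adjusted p = 0.312, adjusted p = 0.721 with an estimated correlation). Without A375 dabrafenib replicate 2 the calls of MITF (-0.59) and of glycolysis (-0.75) ended, glycolysis also without replicate 1 (-0.64), and oxidative phosphorylation lost its call without replicate 3 (-0.19).

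At the extremes, ANGPTL7 was at least 30.6-fold higher with dabrafenib, FOXD3, a neural crest transcription factor, at least 18.6-fold, CCN5 11.5, CLP1 9.08, LRRC15, DUSP7 and SCRG1 8.61, SGCE 8.13, and MAGEA3 and DAGLA 6.69, each against a limit of 3 counts in the DMSO library. CLP1, DUSP7, SGCE, MAGEA3 and DAGLA stood at 7.04 to 20.4 CPM in the other 3 groups, A375-BIR with DMSO included. For these genes the lone DMSO library is the one that stands apart, so their rise cannot be assigned to dabrafenib. KRT18 was at least 19.99-fold lower, BCAT2 at least 15.1, HROB 11.4, CENPM 5.11, UCP2 4.42 and BST2 3.95, each against a limit of 3 counts over the dabrafenib group. BST2 lost its call and its direction with thinned counts. CYB5R2 had a ratio of 95.5 (95% counting interval 16.9 to 3799.8) and SPRR2D of 72.5 (12.7 to 2891), both higher with DMSO. The metallothionein gene MT2A fell by 6.05 ± 0.30 and the potassium channel gene KCNN4 by 5.85 ± 0.45 on the log2 scale. In all, 1833 genes were higher and 2115 lower, 1412 and 1674 of them at least 2-fold. DESeq2 called 1140 and 1345, and thinned counts 540 and 826.

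The lines were also compared in DMSO, again against the lone A375 library and across runs. BRAF was higher in A375-BIR at 53.8 ± 12.1 against 18.8 CPM (1.51 ± 0.33), a call that ended with thinned counts (0.10). With A375 in dabrafenib at 46.0 CPM, the lone A375 DMSO library was again the one apart. Of 9 MAPK output genes, 2 were higher and 6 lower, also adjusted over the list alone, with a median of -0.92, and the list was not called (camera adjusted p = 0.16, adjusted p = 0.422 with an estimated correlation). As in dabrafenib, AXL was higher in A375-BIR, at 373 ± 36.4 against 10.7 CPM (5.10 ± 0.35), EGFR at 197 ± 26.3 against 6.91 CPM (4.81 ± 0.38), SOX10 lower at 41.1 ± 8.48 against 471 CPM (-3.49 ± 0.23) and ERBB3 at 20.7 ± 7.15 against 183 CPM (-3.06 ± 0.26). SPRY4 was lower (-2.67 ± 0.25), and DUSP6 (0.41 ± 0.25) and TOP2A (-0.30 ± 0.22) were not called. Of 23 AXL-high genes, 15 were higher and 2 lower, also adjusted over the list alone (median 1.39, or 1.32 with 1 gene at its bound, camera adjusted p = 1.20e-05, adjusted p = 0.0528 with an estimated correlation). Of 21 YAP/TAZ targets, 16 were higher and 1 lower (16 and 2 adjusted over the list alone), ANKRD1 first at a ratio of 218 (95% counting interval 60.0 to 1800.0), with a median of 2.56, or 2.14 with 2 genes at their bound (camera adjusted p = 5.46e-09, adjusted p = 0.0528 with an estimated correlation). Of 16 receptor tyrosine kinases and ligands, 11 were higher and 1 lower, also adjusted over the list alone (median 1.58, camera adjusted p = 0.00204, adjusted p = 0.0528 with an estimated correlation). Of 19 melanocyte genes, 16 were lower and 1 higher, also adjusted over the list alone (median -3.06, camera adjusted p = 3.77e-12, adjusted p = 0.0528 with an estimated correlation). Of 21 antigen presentation genes, 15 were lower and 2 higher, also adjusted over the list alone, HLA-DRB1 (-4.08) and CD74 (-3.41) among them (median -1.56, camera adjusted p = 5.22e-06, adjusted p = 0.0528 with an estimated correlation). Of 27 interferon genes, 19 were higher and 4 lower, also adjusted over the list alone, with IFI27 at 4.97 and ISG15 at 3.32 (median 1.68, camera adjusted p = 1.22e-05, adjusted p = 0.422 with an estimated correlation). Of 29 G2/M genes, 17 were higher and 1 lower, also adjusted over the list alone, CCNA2 (2.37) and KIF20A (3.24) among them (median 0.79, camera adjusted p = 0.00277, adjusted p = 0.0528 with an estimated correlation). Of 21 hypoxia genes, 15 were higher and 5 lower, also adjusted over the list alone (median 1.07, camera adjusted p = 0.0401, adjusted p = 0.574 with an estimated correlation). Of 13 mitochondrially encoded genes, 11 were lower and 1 higher, also adjusted over the list alone (median -1.60, camera adjusted p = 5.22e-06, adjusted p = 0.574 with an estimated correlation).

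The genes farthest apart in DMSO had at most 3 counts in 1 of the lines. SOX11, a neural transcription factor, was at least 152-fold higher in A375-BIR, GDA 109, TMPRSS15 96.8, HBE1 72.8, MGST1 60.7, IGFBP7 59.8, ADAMTS12 58.4, MUC15 49.2 and TNFRSF10A 47.1, and KISS1 had a ratio of 638 (95% counting interval 114 to 25225). CAPN3 was at least 245-fold lower, ACAN 238, BAALC 179, PIEZO2 163, CYGB 143, the cancer-testis antigen gene CTAG2 114 and TFAP2B 76.3. DCT had a ratio of 576 (159 to 4766), MRGPRX3 of 614 (109.5 to 24326) and SOD3 of 496 (137 to 4107), all higher in A375. In all, 2567 genes were higher and 2731 lower in A375-BIR, 1983 and 1980 of them at least 2-fold. With thinned counts the numbers were 839 and 988, and with a mean count of at least 50 they were 918 and 977.

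The last comparison asked whether the lines responded differently, as the interaction of line and treatment, which again rests on the lone A375 DMSO library. The difference in log2 change was -1.20 ± 0.43 for BRAF, which was called higher with dabrafenib in A375 alone. BRAF stood at 18.8 CPM in the A375 DMSO library and at 46.0 to 57.7 CPM in the other groups. That library was thus the one apart, so this difference cannot be assigned to dabrafenib. Named ERK output and proliferation genes fell less in A375-BIR than in A375, or, as CCND1, did not fall there. The difference was 2.65 ± 0.32 for CCND1, 1.99 ± 0.39 for DUSP6, 3.19 ± 0.48 for SPRY4, 3.08 ± 0.46 for ETV5, 2.60 ± 0.29 for TOP2A and 2.41 ± 0.35 for MKI67. In DMSO, SPRY4 (39.9 against 264 CPM) and ETV5 (56.0 against 124) already stood lower in A375-BIR than in the lone A375 library. CCND1 (474 against 278) and MKI67 (698 against 376) stood higher, and DUSP6 and TOP2A were not called. NGFR had a lower response in A375-BIR (-3.05 ± 0.62), and MITF differed by 0.90 ± 0.29. Of 9 MAPK output genes, 6 had a higher and none a lower response in A375-BIR (6 and 1 adjusted over the list alone, median 1.99, camera adjusted p = 5.78e-05, adjusted p = 0.0623 with an estimated correlation). Of 13 other ERK-dependent genes 4 were higher (5 and 1 lower adjusted over the list alone), EGR1 (2.45) among them, with a median of 1.18 (camera adjusted p = 0.0293, adjusted p = 0.247 with an estimated correlation). Of 29 G2/M genes 17 were higher (19 adjusted over the list alone), BIRC5 (2.46) and TPX2 (1.61) included, with a median of 1.35 (camera adjusted p = 1.17e-07, adjusted p = 0.0623 with an estimated correlation). Of 24 S phase genes 13 were higher, also adjusted over the list alone, with MCM7 at 2.71 and CDT1 at 2.73 (median 1.38, camera adjusted p = 2.97e-05, adjusted p = 0.183 with an estimated correlation). Of 22 matrix genes 8 were higher and 2 lower (9 and 2 adjusted over the list alone), such as COL4A2 (1.75), SPARC (1.43) and TIMP3 (1.51), with a median of 0.84 (camera adjusted p = 0.00906, adjusted p = 0.221 with an estimated correlation). Of 30 ribosome biogenesis genes 13 were higher and 2 lower (15 and 2 adjusted over the list alone), with BOP1 at 2.49 (median 1.04, camera adjusted p = 0.000972, adjusted p = 0.216 with an estimated correlation). Of 21 hypoxia genes 9 were lower, also adjusted over the list alone, with ANKRD37 at -4.63 (median -0.76, camera adjusted p = 2.97e-05, adjusted p = 0.216 with an estimated correlation). Of 9 cancer-testis antigen genes 4 were lower, also adjusted over the list alone, with MAGEA12 at -3.19 (median -0.75, camera adjusted p = 0.00636, adjusted p = 0.248 with an estimated correlation). Of 59 ribosomal protein genes 36 were higher (39 adjusted over the list alone), with RPL6 at 2.30 (median 1.38, camera adjusted p = 5.57e-19, adjusted p = 0.336 with an estimated correlation). The call of BRAF in this comparison ended without A375-BIR DMSO replicate 1 or 3 or A375 dabrafenib replicate 1 or 2 (-1.22 to -1.03), with no filter on low counts (-1.14), by DESeq2 (-1.19) and with thinned counts (-0.046). The call of MITF ended without A375-BIR DMSO replicate 1 or 2 or A375 dabrafenib replicate 2 (0.78 to 0.88), and that of the other ERK-dependent genes without the last (1.12). Thinning also ended those of DUSP6 (1.73), NGFR (-2.79), COL4A2 (0.90) and TPX2 (1.21). In all, 1303 genes had a higher and 1010 a lower response in A375-BIR, 1174 and 920 of them by at least 2-fold. The counts were 689 and 464 by DESeq2, and 339 and 165 with thinned counts.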

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

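The tests of the fall in A375 given in this part were all chosen after that result was seen. Results are listed here because the interaction term of the edgeR fit called a difference between the responses of A375-BIR and A375, or because a file outside the comparisons held a signal. Every interaction value uses the lone A375 DMSO library of the other run.

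The response to dabrafenib was higher in A375-BIR for 1303 genes and lower for 1010. Lists with a higher response were MAPK output (median difference in log2 change 1.99), the other ERK-dependent genes (1.18), S phase (1.38), G2/M (1.35), the matrix genes (0.84), ribosome biogenesis (1.04) and the ribosomal proteins (1.38). Lists with a lower response were hypoxia (-0.76) and the cancer-testis antigens (-0.75). All 9 list calls were lost with an estimated correlation (adjusted p = 0.0623 to 0.336).

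Among named genes, the difference in log2 change was positive for KCNN4 (5.57), MT2A (5.37), C1R (4.09), ETV4 (3.76), SPRY4 (3.19), ETV5 (3.08), CDT1 (2.73), MCM7 (2.71), CCND1 (2.65), TOP2A (2.60), BOP1 (2.49), BIRC5 (2.46), EGR1 (2.45), MKI67 (2.41), GAPDH (2.37), RPL6 (2.30), RPS28 (2.26), CLSPN (2.25), CDC20 (2.22), IER3 (2.19), PIF1 (2.01), DUSP6 (1.99), NDUFB10 (1.97), RPS20 (1.85), LYAR (1.79), COL4A2 (1.75), ENO1 (1.71), PLK1 (1.70), UQCRC1 (1.67), TPX2 (1.61), TIMP3 (1.51), EFNA5 (1.48), TGFBI (1.48), SPARC (1.43), AURKA (1.35), FBL (1.24) and MITF (0.90). It was negative for ARHGEF10L (-5.80), ANKRD37 (-4.63), PCK2 (-3.23), MAGEA12 (-3.19), NGFR (-3.05), HILPDA (-2.96), CNN3 (-2.91), ANXA1 (-2.75), AMOTL2 (-2.50), SEC24D (-2.11), SLC2A1 (-2.0), DDIT3 (-1.92), LATS2 (-1.27), BRAF (-1.20), ASNS (-1.11), SEMA3C (-0.98) and THBS1 (-0.84). The calls of BRAF and MITF ended without any 1 of several libraries. Without 1 library at which they ended, the values changed little, ranging from -1.22 to -1.03 and from 0.78 to 0.88. Thinned counts also ended the call of BRAF, as given above. At BRAF the lone A375 DMSO library, at 18.8 CPM, stood apart from the other groups.

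Further named genes had at most 3 counts in at least 1 group, so their fitted differences are no bound. On the positive side they were BCAT2 (8.25), KRT18 (8.25), HROB (8.10), SPRR2D (7.94), BST2 (6.79), UCP2 (6.78), OASL (6.29), CENPM (6.23), C1QTNF1 (6.14), SCAMP5 (5.87), CYB5R2 (4.78) and C3 (4.18). On the negative side they were FOXD3 (-7.50), MAGEA3 (-7.09), CLP1 (-6.57), SGCE (-6.51), DUSP7 (-6.15), DAGLA (-5.97), WASF1 (-5.29), L3HYPDH (-5.16) and FOXF2 (-5.14). MAGEA3, CLP1, SGCE, DUSP7 and DAGLA were at 0 in the A375 DMSO library only, and at 7.04 to 20.4 CPM in the other 3 groups. BCAT2, KRT18, BST2, UCP2, OASL and CENPM were at 0 in A375 with dabrafenib only, and at 9.42 to 209 CPM in the others. BST2 lost its call and its direction with thinned counts (-0.022).

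The files of the second and the third A375 DMSO library held 224221 and 652439 gene counts on mouse identifiers. A single mouse gene took 41.2% and 39.9% of them, and 6420 and 7445 mouse genes were detected, against 14920 human genes in the first library. Across the 8135 genes with a count in either file, log2 levels correlated at 0.823, where genes are not independent replicates. Whether human reads were counted on a mouse annotation, or the libraries came from mouse material, was not tested.

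The lower ERK output in A375 with dabrafenib, the action for which the drug is given, rests on 1 DMSO library of another run. A library of A375-BIR cells under an A375 label was argued against: of 7 genes seen in A375 with dabrafenib and at 0 in every A375-BIR library, 6 (85.7%) reached 10 CPM in it. Of the line genes at large, 61.5% (1556 of 2531) lay nearer to A375 with dabrafenib, between the bounds set for that test, which by itself decides nothing. Of 10000 random lists matched on expression, 0% had a median as low as that of the MAPK output list, but 0% also had one as low as that of the ribosomal proteins (-1.38), so this does not part a run difference from the drug. A culture or library difference that came with the run may explain part of the fall and cannot be told apart from the drug, as 0 usable A375 DMSO libraries came from the run of the dabrafenib libraries. Among genes at 5 CPM or more in the other 3 groups, 15 were at 0 in A375 DMSO and 14 in A375 with dabrafenib. The number was 0 for each A375-BIR group. At 56.1% of the genes called in the response of A375, the DMSO library was also called apart, the same way, from A375-BIR with DMSO. At a smaller share of those genes, A375 with dabrafenib was the group apart from both. These counts and shares do not part the run from the drug either.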

How the results depend on the processing

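Of the alternatives, a fit without the A375 DMSO library and one without the third dabrafenib libraries of both lines were chosen after the data were seen. Over the alternatives, named genes kept their direction and their side of the threshold in 2246 of 2522 values in the response of A375-BIR, 1861 of 1954 in that of A375, 1750 of 1790 between the lines in DMSO, 2462 of 2515 between them in dabrafenib and 2477 of 2700 in the difference between responses. Calls were lost in 179, 75, 30, 43 and 173 of these values and gained in 66, 5, 2, 1 and 23. A called gene lost both its call and its direction in 0, 1, 0, 0 and 1. In the other 31, 12, 8, 9 and 26, a gene not called changed or lost its sign. For lists described in the report, 332 of 391, 146 of 168, 105 of 116, 270 of 301 and 152 of 170 values kept both, over the comparisons in the same order. In no alternative was a gene called in the opposite direction to its call here.

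DESeq2 size factors in edgeR, the removal of mitochondrially encoded genes and limma-voom left every count of called genes within 1.5 times its value and ended no list call. With the replicate block 239 genes were called in the response of A375-BIR, 231 of them among the 252. Residuals of same-numbered libraries correlated at -0.33 to 0.25 over 3336 genes, and those of differently numbered libraries at -0.23 to 0.38. They thus show no pairing by number, but with 3 libraries per group they cannot exclude a shared culture or batch.

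In the response of A375-BIR, the counts of 139 genes higher and 113 lower became 77 and 60 with a mean count of at least 50, 33 and 28 with thinned counts, 59 and 47 by DESeq2 and 69 and 56 with only the groups compared in the fit, and ranged from 54 to 301 and from 44 to 257 without 1 library. With thinned counts, calls were lost for MAPK output (-0.40), antigen presentation (0.23), drug efflux (0.53) and axon guidance (0.21). With no filter, calls were lost for NF-kB (0.47), drug efflux (0.26), other ERK genes (-0.11), axon guidance (0.21), histones (-0.27) and interferon (0.26). With a mean count of at least 50, calls were lost for NF-kB (0.48), YAP/TAZ (0.22), antigen presentation (0.24), AXL-high (0.10), axon guidance (0.57) and interferon (0.27). With only the groups compared in the fit, calls were lost for NF-kB (0.17) and heat shock (-0.22). With the A375 DMSO library left out of the fit, the call was lost for NF-kB (0.15). Without the third dabrafenib libraries of both lines, calls were lost for drug efflux (0.16), other ERK genes (-0.34), oxidative phosphorylation (-0.062) and heat shock (-0.18). The test of a list not called changed direction with a mean count of at least 50 for CDK inhibitors (0.035) and pathway components (0.11), with thinned counts for CDK inhibitors (0.12) and pathway components (0.040) and with only the groups compared in the fit for pathway components (-0.0070). Thinning turned the direction of the NF-kB test and ended its call (median 0.042). An estimated correlation ended the calls of MAPK output (-0.36), NF-kB (0.45), YAP/TAZ (0.26), antigen presentation (0.34), cholesterol (-0.49), AXL-high (0.12), drug efflux (0.32), ATF4 targets (0.58), other ERK genes (-0.30), oxidative phosphorylation (-0.21), axon guidance (0.38), heat shock (-0.24), histones (-0.71) and interferon (0.40). Leaving out 1 library at a time changed the call, or the direction of the test, at 1 or more libraries for lists whose medians ranged from -0.18 to 0.17 (ER stress), 0.23 to 0.70 (NF-kB), -0.15 to 0.078 (pathway components), 0.21 to 0.36 (YAP/TAZ), 0.32 to 0.48 (antigen presentation), 0.086 to 0.25 (AXL-high), -0.065 to 0.18 (lysosome), -0.42 to -0.16 (other ERK genes), 0.050 to 0.46 (fibroblast markers), -0.37 to -0.043 (oxidative phosphorylation), -0.27 to -0.17 (heat shock) and 0.15 to 0.47 (interferon).

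For the response of A375, the counts of 1833 genes higher and 2115 lower became 818 and 851 with a mean count of at least 50, 540 and 826 with thinned counts and 1140 and 1345 by DESeq2. With a mean count of at least 50, calls were lost for YAP/TAZ (0.59), glycolysis (-0.70), oxidative phosphorylation (-0.15) and ribosome biogenesis (-0.56). With no filter, calls were lost for glycolysis (-0.68) and neural crest (1.31). With only the groups compared in the fit, the call was lost for glycolysis (-0.73). With the replicate block, the call was lost for oxidative phosphorylation (-0.26). Without the third dabrafenib libraries of both lines, the call was lost for oxidative phosphorylation (-0.19). Thinning ended the call of BST2 and its direction (fitted log2 0, against -6.02 before). An estimated correlation ended the calls of S phase (-1.47), YAP/TAZ (0.76), glycolysis (-0.71), hypoxia (1.03), ATF4 targets (1.05), neural crest (1.39), other ERK genes (-0.65), oxidative phosphorylation (-0.29), ribosome biogenesis (-0.94) and ribosomal proteins (-1.38). Leaving out 1 library at a time changed the call, or the direction of the test, at 1 or more libraries for lists whose medians ranged from -0.75 to -0.64 (glycolysis) and -0.44 to -0.19 (oxidative phosphorylation).

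Between the lines in DMSO, the counts of 2567 genes higher and 2731 lower became 918 and 977 with a mean count of at least 50 and 839 and 988 with thinned counts. With a mean count of at least 50, the call was lost for G2/M (0.72). With thinned counts, the call was lost for hypoxia (1.00). An estimated correlation ended the calls of G2/M (0.79), YAP/TAZ (2.56), antigen presentation (-1.56), AXL-high (1.39), hypoxia (1.07), melanocyte (-3.06), receptor kinases (1.58), mitochondrial (-1.60) and interferon (1.68).

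Between the lines in dabrafenib, the counts of 2309 genes higher and 2065 lower became 900 and 864 with a mean count of at least 50 and 1292 and 1201 with thinned counts. With a mean count of at least 50, calls were lost for NF-kB (1.2), neural crest (-0.31), receptor kinases (1.32) and nuclear RNAs (-1.30). With thinned counts, calls were lost for NF-kB (1.06), neural crest (-0.53) and receptor kinases (1.18). With only the groups compared in the fit, calls were lost for NF-kB (1.02) and nuclear RNAs (-1.20). With no filter, calls were lost for epithelial (0.65) and receptor kinases (1.12). An estimated correlation ended the calls of S phase (1.34), G2/M (2.18), NF-kB (1.31), YAP/TAZ (1.53), antigen presentation (-0.74), AXL-high (1.91), ATF4 targets (-0.92), melanocyte (-2.53), neural crest (-1.10), epithelial (6.67), p53 (-0.52), receptor kinases (1.33), ribosome biogenesis (0.58), mitochondrial (-1.20), nuclear RNAs (-1.18), ribosomal proteins (0.76) and interferon (2.81). Leaving out 1 library at a time changed the call, or the direction of the test, at 1 or more libraries for lists whose medians ranged from -0.71 to -0.45 (p53) and -1.50 to -0.94 (nuclear RNAs).

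In the difference between the responses, the counts of 1303 genes higher and 1010 lower became 619 and 514 with a mean count of at least 50, 339 and 165 with thinned counts and 689 and 464 by DESeq2. With a mean count of at least 50, calls were lost for S phase (1.35), matrix (1.07), other ERK genes (1.09) and ribosome biogenesis (0.58). With thinned counts, calls were lost for matrix (0.93) and cancer-testis (-0.57). With no filter, the call was lost for cancer-testis (-0.42). With the replicate block, the call was lost for other ERK genes (1.01). Thinning ended the call of BST2 and its direction (fitted log2 -0.022, against 6.79 before). An estimated correlation ended the calls of S phase (1.38), G2/M (1.35), MAPK output (1.99), matrix (0.84), hypoxia (-0.76), cancer-testis (-0.75), other ERK genes (1.18), ribosome biogenesis (1.04) and ribosomal proteins (1.38). Leaving out 1 library at a time changed the call, or the direction of the test, at 1 or more libraries for lists whose medians ranged from 0.66 to 1.18 (other ERK genes).

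The stricter filter tested 3336 genes and thinning left 6933, which by construction lowers the counts of calls. Each library left out also lowers the number of libraries. DESeq2 gave no adjusted p for 3572 genes in the response of A375-BIR and 1588 in the difference between responses. For the other changes the cause was not tested. For lists the values above in parentheses are medians of log2 changes. Epithelial genes at 0 in A375 with dabrafenib have fitted values that are no bound, so their median of 6.67 depends on the fit. Depth limits the smallest library, with 198690 gene counts, to levels above 15.1 CPM of its raw total for a count of 3. The lone A375 DMSO library could not be left out of the comparisons that use it, and no alternative replaces it. A fit with only the groups compared was not run for the difference between responses, which needs all 4.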

Other observations

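The tests of carry-over in this part, and the values on A375 cells in A375-BIR, were chosen after the results were seen. Those on a different line, thinned counts, the library with the highest MALAT1 share and other splits were set before.

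The lines stood far apart in dabrafenib, with 4374 genes called. The highest count over the other 9 splits of the 6 libraries was 0. Each of those splits mixes the lines within a group, which widens the spread, so a low count was built in. The splits are also too few for a share under 0.05, and nothing is concluded from them. Unchanged A375 cells in the A375-BIR libraries would shrink that distance, so they were not weighed as its cause, and 41 of 3386 genes at 50 CPM or more in every A375 dabrafenib library lay under 5% of that level in A375-BIR. A different line in place of an A375 derivative may explain the distance: the longest stretch of neighbouring genes at 0 in A375 and expressed in A375-BIR was 2 genes, as long as in 543 of 1000 shuffled orders, which decides nothing. Lasting changes in a resistant derivative, which the labels name, remain untested beside it.

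The fall of mitotic genes in A375-BIR with dabrafenib stood beside 252 called genes, against a highest count of 0 over the other splits. Those splits mix DMSO and dabrafenib libraries within a group and are again too few for a share under 0.05, so they decide nothing. Lower depth was argued against by thinned counts, with a G2/M median of -0.93, and so was the library with the highest MALAT1 share, with -0.88 without it. Carry-over of A375 dabrafenib reads may explain the rise of DCT, since 19 genes nearly absent from A375-BIR with DMSO held 194% of the counts (55 against 28.4) that the needed share of 0.870% predicts, or 91.1% without ANGPTL7 (25 against 27.4), where the deeper DMSO libraries already held 11. The counts of those 18 genes did not follow 1 ratio to A375 with dabrafenib by a chi-square test (p = 0.0005 from simulated draws), with 8 of them at 0. That test took off none of A375-BIR's own counts of these genes, so it decides nothing on a share common to all. ACAN at 0 limited such a share to 0.598%, but with so few counts carry-over as the source of DCT stays open. As the source of ANGPTL7, carry-over was argued against, since the other 18 genes held 3.06% of the counts that its share of 25.9% predicts.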
